A study of Mus musculus with 13 samples.

How the data were processed

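Gene expression was measured with a mouse whole-transcript Affymetrix gene array in 13 samples of epithelium that had been freed from the underlying tissue with dispase. The samples came from animals with L2-Cre, either wild type for p120-catenin or with floxed alleles of its gene, Ctnnd1 (p120 flox/flox), on a mixed C57Bl/6 and 129 background. Total RNA was extracted with Trizol and labelled with biotin. The deposited values are intensity values on a linear scale, made by the authors with GCRMA, a background correction and summary of the probes that uses their sequence; its version was not given in the sources used here. Raw array files were not used here. The median intensity per array lay between 65.3 and 72.4 and the maximum between 20585 and 21860, and the number of arrays limits the precision.

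The table held 34729 probe sets. Of these, 21633 were listed with 1 gene, 1306 with several and 11790 with none. Values below 1 were set to 1 and all values were put on the log2 scale. A probe set entered the test if its log2 intensity was above 5 on at least 3 arrays, and each gene was represented by the probe set with the highest mean. This left 15875 genes of 19934, and 4059 fell below the filter. A RefSeq gene table was used for gene names and for the neighbours of Ctnnd1; no symbol had to be changed, and 21546 probe sets with 1 gene were found in it. The array's RNA-quality control probes were not analysed here.

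Group means were fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, default settings), in 1 fit of all 13 arrays with a mean for each of the 4 groups and 9 residual degrees of freedom. The p-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. The 4 comparisons were flox/flox against control esophagus, flox/flox forestomach mass against control forestomach, the difference of these changes, and control forestomach against control esophagus. The comparisons of flox/flox with control are called genotype comparisons below. Every flox/flox forestomach sample was a mass, so the forestomach comparison and the difference cannot separate genotype from the formation of a mass. Changes are given as log2 differences of group means with the standard error (SE) of the fit. All numbered replicates are different animals, except that the 3 control animals 214, 216 and 217 each gave an esophagus and a forestomach. Whether the arrays of an animal belong together was checked from the deviations of the control arrays from their group means. These correlated at 0.401, 0.398 and 0.315 across genes between the tissues of animals 214, 216 and 217, and at -0.425 to 0.129 between different animals.

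The text names Ctnnd1 and 8 sentinel genes (Cdh1, Ctnnb1, Ctnna1, Cdh3, Jup, Krt5, Krt13 and Ptprc). It also names the 8 largest rises and 8 largest falls among called genes whose groups do not overlap. From each gene list up to 4 called members are taken by the smallest adjusted p, at most 2 from a list that did not pass its own test. For the difference and for the control tissues the 5 largest changes each way are named; predicted and RIKEN genes are skipped. This rule, the comparisons, the gene lists and all alternatives except those said to be added were fixed before the data were examined.

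The 35 gene lists held 613 different genes, of which 517 were tested and 8 are in more than 1 list. Junction lists covered the adherens junction, the desmosome and the tight junction. Epithelial lists covered basal squamous cells, squamous differentiation, stress keratins and alarmins, proliferation, xenobiotic and retinoid metabolism, and lipid metabolism. Signalling and response lists covered NF-kappaB target genes, cytokines and chemokines, interferon-stimulated genes, EGFR ligands and receptors, Wnt and beta-catenin targets, the Notch pathway, hypoxia and glycolysis, the immediate early and handling response, mesenchymal transition, and matrix proteases. Cell type lists covered MHC class II presentation, Langerhans and dendritic cells, macrophages and monocytes, neutrophils and immature myeloid cells, T and NK cells, B and plasma cells, mast cells, fibroblasts and matrix, activated fibroblasts and pericytes, endothelial cells, skeletal muscle, smooth muscle, adipocytes, glandular stomach, and submucosal gland and salivary. Of the lists, 1 more was tested and counted and is not described here. Lists with at least 5 members tested, 34 of the 35, were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. The submucosal gland and salivary list had 2 members tested and got no test. Beside camera, each list was tested with the correlation estimated from its own genes, and with fry, which asks whether the members move, on balance, 1 way.

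Alternatives were no filter and a stricter filter (log2 intensity above 7), all probe sets and the mean of a gene's probe sets, quantile normalization, median centring, only the arrays compared, eBayes with trend and robust, array weights, a 2-fold minimum, an adjusted p under 0.01, the animal as a block, and leaving out each array in turn. After the data were seen, further kinds of alternative were added: the sex of the animal as a covariate (read from Xist and Y-linked genes), the mean of the skeletal muscle list per array as a covariate, the esophagus comparison without arrays 214, 307 and 335, the forestomach comparison without mass 426 with forestomach arrays alone, and the correlation of the 2 genotype changes with no control animal in both. Camera on the ranked statistics, with and without the animal as a block, was also added outside the plan.

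The test was also run on simulated data with 50 genes changed at each size. In the esophagus design it recovered 36% of genes changed 1.5-fold, 86% at 2-fold, 98% at 4-fold and 100% at 8-fold, with 7 false calls. In the forestomach design it recovered 30%, 76%, 98% and 96% at the same sizes, with 8 false calls. In both designs 0 genes were called with the wrong sign. These shares may not hold for genes that vary more between animals. They may also be too high for a comparison in which fewer genes change, since the adjustment is then stricter. On the real esophagus arrays Krt6a was not called, at 8.33 to 10.91 in flox/flox animals and 6.01 to 6.50 in controls.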

Results

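Expression was measured in epithelium from 7 esophagus samples and 6 forestomach samples. The esophagus samples came from 3 control animals (214, 216 and 217) and 4 p120 flox/flox animals (193, 307, 313 and 335). The forestomach samples came from the same 3 control animals and from masses of 3 other flox/flox animals (412, 426 and 510). Values are log2 intensities. Within groups, arrays correlated at 0.948 to 0.991 in control esophagus, 0.952 to 0.978 in flox/flox esophagus, 0.986 to 0.992 in control forestomach and 0.918 to 0.941 among the masses. The median SD of a gene was 0.137, 0.148, 0.115 and 0.248 in these groups. The leading principal component held 30.9% of the variance and the next 23.8%. Animals 214, 193, 313, 335, 412 and 426 expressed Xist and lacked Y-linked transcripts, and 216, 217, 307 and 510 expressed Y-linked genes, so both sexes were present in every group.

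Ctnnd1, the gene of p120-catenin, which binds classical cadherins at adherens junctions, was read by 1 probe set. In esophagus its level was 10.33, 10.50 and 10.21 in controls 216, 217 and 214, and 10.13, 9.95, 10.08 and 10.04 in flox/flox animals 193, 307, 313 and 335. The difference of -0.29 (SE 0.11, n = 3 and 4) did not pass the test (limma adjusted p = 0.637), although the groups did not overlap. In forestomach the level was 10.40, 10.14 and 10.23 in controls 214, 216 and 217, and 9.66, 9.91 and 9.51 in masses 412, 426 and 510. It fell by 0.56 (SE 0.12, n = 3 and 3, 1.47-fold, adjusted p = 0.0145). That call was lost without forestomach control 214 (adjusted p = 0.0678), with only the forestomach arrays in the fit (0.0945), with array weights (0.0510) and without mass 426 with forestomach arrays alone (0.0554). The deleted exons and the positions of the probes are not given in the sources used here, so these values may not measure the deletion.

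**Figure D1:**
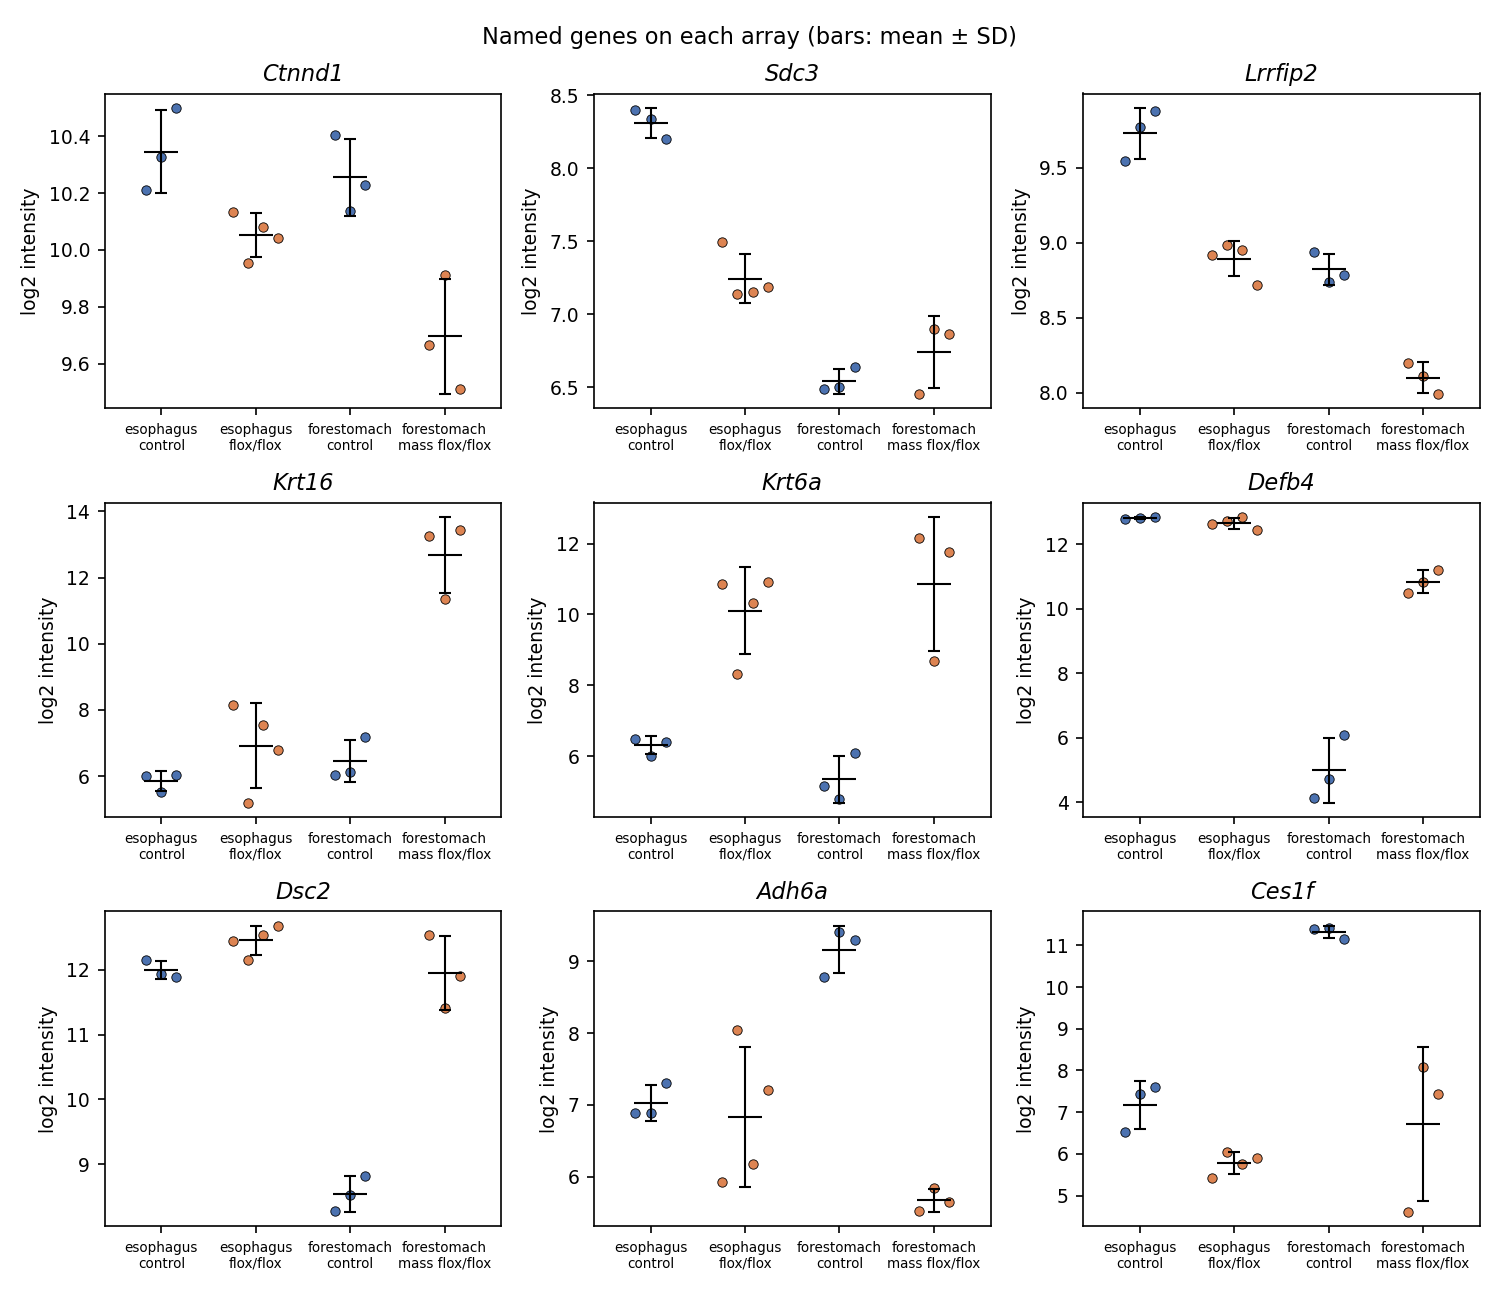
Log2 intensity of 9 genes on each of the 13 arrays, by group; dots are arrays and bars are group means with SD. Krt16 averaged 6.45 in control forestomach and 12.68 in the masses, and Ces1f 11.32 and 6.71.

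In the esophagus, the comparison of p120 flox/flox with control epithelium found 2 genes, both lower in flox/flox. Sdc3, which encodes the cell-surface proteoglycan syndecan-3, fell by 1.07 (SE 0.13, 2.10-fold, limma adjusted p = 0.0400). Its mean was 8.31 ± 0.10 (SD, n = 3) in controls and 7.24 ± 0.17 (SD, n = 4) in flox/flox animals, where animal 193 stood at 7.49 and the others between 7.14 and 7.19. Lrrfip2, whose product takes part in innate immune and Wnt signalling, fell by 0.84 (SE 0.11, 1.79-fold, adjusted p = 0.0400), from 9.73 ± 0.17 to 8.90 ± 0.12. Among the junction and keratin sentinels, E-cadherin (Cdh1) differed by 0.17 (SE 0.11, adjusted p = 0.856), P-cadherin (Cdh3) by 0.9965 (SE 0.36, adjusted p = 0.587), Ctnnb1 by 0.11, Ctnna1 by -0.08, Jup by 0.10, Krt5 by -0.01 and Krt13 by -0.10. The leukocyte gene Ptprc differed by 1.28 (SE 0.62, adjusted p = 0.736). None of these 8 passed the test. At an unadjusted p under 0.05 there were 1108 genes, where chance gives 794.

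The esophagus count of 2 depended on single arrays. It was 7 without flox/flox animal 307, 3 without esophagus control 214, 1 without flox/flox animal 193 or mass 412, and 0 without any other array. Sdc3 was lost without esophagus controls 216, 217 and 214 (adjusted p = 0.410, 0.185 and 0.0834), flox/flox 313 and 335 (0.0992 and 0.161), forestomach controls 214, 216 and 217 (0.0734, 0.0953 and 0.104) and masses 426 and 510 (0.0508 and 0.0535). Lrrfip2 was lost without esophagus controls 216 and 217 (adjusted p = 0.410 and 0.411), flox/flox 193, 313 and 335 (0.173, 0.0992 and 0.161), forestomach controls 214, 216 and 217 (0.0734, 0.0953 and 0.116) and masses 412, 426 and 510 (0.0582, 0.0667 and 0.0535). With the animal as a random block the adjusted p was 0.0593 for Sdc3 and 0.0975 for Lrrfip2.

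Of the 34 gene lists, 13 passed camera in the esophagus at the preset correlation and 0 with an estimated correlation or with fry. Other splits of the esophagus arrays passed a median of 11 lists by camera at the preset correlation. A list that passed is therefore weak evidence of a difference between the genotypes. No list member was called over all genes, and 58 of the 517 different genes had an unadjusted p under 0.05 by limma. Antigen presentation by MHC class II lay above 0 in 9 of 9 genes (median 1.13, adjusted p = 5.08e-05), with array means of 8.40 in animal 193 and 8.31 in 335 and between 6.11 and 7.40 on the other esophagus arrays. T and NK cell genes rose as a group (10 of 11 above 0, median 0.43, adjusted p = 0.00194), as did Langerhans and dendritic cell genes (8 of 9 above 0, median 0.23, adjusted p = 0.00486). The T and NK cell mean was 7.07 in animal 193 and between 5.54 and 6.17 on the other esophagus arrays. Squamous differentiation fell as a group (26 of 27 below 0, median -0.19, adjusted p = 5.08e-05), with means of 10.64 and 10.68 in animals 193 and 335, 11.01 and 11.02 in 307 and 313, and 11.06 to 11.10 in controls. Xenobiotic and retinoid metabolism, the enzymes that oxidise and conjugate foreign compounds and retinol, fell as a group (17 of 21 below 0, median -0.39, adjusted p = 5.98e-05). All 5 of these lists had adjusted p = 0.686 with an estimated correlation and passed camera without any single array. Adjusted over the list alone, 1 xenobiotic gene was lower and 0 genes of the other 4 lists passed; it was Gstm2 (-1.0005, SE 0.25), named after its value was seen.

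Stress keratins and alarmins, which mark wounded or inflamed squamous epithelium, rose in the esophagus (12 of 19 genes above 0, median 0.94, adjusted p = 0.0127, and adjusted p = 0.715 with an estimated correlation). The list's mean was 10.33, 9.83 and 9.91 in flox/flox animals 193, 313 and 335, 8.85 in 307, and between 8.575 and 8.996 in controls. Adjusted over the list alone, 2 genes were higher, Krt6a (3.81, SE 0.79) and Krt6b (3.39, SE 0.74), named after their values were seen; over all genes their adjusted p was 0.332 and 0.340. The list missed the threshold without esophagus control 216 or 214 (adjusted p = 0.0601 and 0.0633) or flox/flox 313 (0.0707). Proliferation rose as a group (23 of 26 above 0, median 0.29, adjusted p = 0.00194, and adjusted p = 0.715 with an estimated correlation) and was lost without control 214 or flox/flox 313 (0.0625 and 0.406), whose mean of 8.22 stood above the 7.15 to 7.63 of the other esophagus arrays. Lipid metabolism fell as a group (16 of 20 below 0, median -0.18, adjusted p = 0.00790, and adjusted p = 0.686 with an estimated correlation) and was lost without flox/flox 193 (0.0780). NF-kappaB target genes rose as a group (12 of 17 above 0, median 0.18, adjusted p = 0.0113, and adjusted p = 0.686 with an estimated correlation) and were lost without control 216 or flox/flox 193 (0.0789 and 0.0572). Interferon-stimulated genes rose as a group (13 of 15 above 0, median 0.19, adjusted p = 0.0138, and adjusted p = 0.703 with an estimated correlation) and were lost without controls 216 and 214 and flox/flox 193 and 335 (0.452, 0.155, 0.0851 and 0.171).

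Skeletal muscle genes were above 0 in 19 of 19 in the esophagus (median 0.66, adjusted p = 0.0187, and adjusted p = 0.820 with an estimated correlation), and 3 arrays carried them. Their mean was 8.22 in control 214, 7.92 in flox/flox 307 and 9.54 in flox/flox 335, and between 5.45 and 5.71 on the other 4 esophagus arrays. Fibroblast and matrix genes stood high on the same arrays, at 9.28, 8.13 and 8.46 against 6.00 to 6.18. Endothelial genes did too, at 7.25, 6.81 and 7.24 against 5.38 to 5.75. The muscle list was lost without control 216 or 217 or flox/flox 307 (adjusted p = 0.480, 0.522 and 0.328), and its median was -0.13 without flox/flox 335. Macrophage and monocyte genes rose as a group (14 of 15 above 0, median 0.29, adjusted p = 0.0127, and adjusted p = 0.715 with an estimated correlation), with means of 7.61, 6.61 and 7.45 on the same arrays and 5.55 to 6.55 on the other 4. They were lost without controls 216 and 217 and flox/flox 335 (0.557, 0.394 and 0.357). Matrix proteases rose as a group (12 of 16 above 0, median 0.15, adjusted p = 0.0138, and adjusted p = 0.686 with an estimated correlation) and were lost without controls 216 and 217 and flox/flox 307 and 335 (0.0822, 0.0618, 0.0564 and 0.105). With sex as a covariate, which is not balanced in the esophagus (1 of 3 controls and 3 of 4 flox/flox animals were female), the lists of NF-kappaB targets (adjusted p = 0.0836), interferon-stimulated genes (0.0610), macrophages (0.340), skeletal muscle (0.0836) and matrix proteases (0.0517) were lost. With the mean of the muscle list as a covariate, macrophages (0.325) and matrix proteases (0.0860) were lost. The muscle list itself cannot be tested that way. Adjusted over the list alone, 0 genes passed in these 3 lists and in the proliferation, lipid, NF-kappaB and interferon lists.

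The other 21 lists did not pass in the esophagus, and 20 are given here. Median changes were -0.02 for the adherens junction, with a mean of 0.03 (adjusted p = 0.828), 0.07 for the desmosome (0.480), -0.04 for the tight junction (0.530) and 0.13 for basal squamous cells (0.480). Cytokines and chemokines had a median of 0.06 and a mean of -0.02 with a test direction of higher (0.708), neutrophils 0.10 (0.993), B and plasma cells 0.00 (0.530), mast cells -0.04 (0.828), adipocytes 0.29 (0.0801), smooth muscle -0.01 with a mean of 0.06 (0.941) and glandular stomach -0.02 with a mean of 0.01 (0.969). Fibroblast and matrix genes had a median of -0.00 and a mean of 0.02 with a test direction of lower (0.993), activated fibroblasts and pericytes a median of -0.01 and a mean of 0.10 (0.941), and endothelial cells a median of 0.11 (0.929). Mesenchymal transition had a median of 0.02 (0.969), EGFR ligands and receptors -0.02 (0.941), Wnt and beta-catenin targets -0.03 (0.179), the Notch pathway -0.01 (0.530), hypoxia and glycolysis -0.11 (0.121) and the immediate early response -0.07 (0.811). Adjusted over the list alone, 4 genes passed in these lists and are named after their values were seen, Dsg3 (1.03, SE 0.19), Xbp1 (0.57, SE 0.14), Flt1 (-1.08, SE 0.30) and Wnt5a (-1.60, SE 0.37). Without esophagus control 214 the lists of fibroblasts and matrix (median 0.89, adjusted p = 1.92e-07), activated fibroblasts (0.0215), endothelial cells (0.00250), smooth muscle (0.0116), adipocytes (0.0490) and mesenchymal transition (0.00250) passed. All 6 were then higher. Without control 217 fibroblasts and matrix (median -0.53, adjusted p = 0.0205) and hypoxia and glycolysis (median -0.17, adjusted p = 0.0149) passed as lower, and without flox/flox 193 or 313 adipocytes passed as higher (0.00270 and 0.01005).

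In the forestomach, flox/flox masses differed from control epithelium in 1700 genes, 366 higher and 1334 lower, and 167 and 308 of them by at least 2-fold. The SE of a gene rests on 1 spread pooled over the 4 groups. The masses varied more than the other groups, with a median SD of 0.248 against 0.115 in control forestomach. In comparisons with the masses, SE and p-values can therefore be too small. The keratin gene Krt16 rose 75.4-fold (log2 6.24, SE 0.70, limma adjusted p = 0.000742), from 6.45 ± 0.64 (SD, n = 3) to 12.68 ± 1.16 (SD, n = 3), and Krt6a rose by 5.52 (SE 0.85, adjusted p = 0.00293), from 5.35 to 10.86. The beta-defensin Defb4 rose by 5.85 (SE 0.37, adjusted p = 4.81e-05) and the serine protease Tmprss11b by 5.65 (SE 0.68, adjusted p = 0.00105), both from control means under the level filter of 5 (4.99 and 4.47). The chitinase-like genes Chil4 and Chil3 rose by 7.05 (SE 1.80, adjusted p = 0.0289) and 4.45 (SE 1.27, adjusted p = 0.0446), the calgranulin S100a8 by 5.43 (SE 1.27, adjusted p = 0.0196) and the tetraspanin Tspan8 by 4.44 (SE 1.22, adjusted p = 0.0386). Chil3 and Tspan8 also had control means under the filter, 4.17 and 4.38. Tspan8 was 10.45 in mass 412, 10.98 in 426 and 5.02 in 510. Without mass 426 the changes were 6.90 for Krt16, 6.60 for Krt6a, 6.75 for S100a8 and 5.92 for Chil3. They were 7.28 for Chil4, 6.44 for Tmprss11b, 5.85 for Defb4 and 3.36 for Tspan8.

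Among the largest falls in the masses, the carboxylesterase Ces1f fell by 4.61 (SE 0.67, limma adjusted p = 0.00233), from 11.32 ± 0.15 (SD, n = 3) to 6.71 ± 1.85 (SD, n = 3). The alcohol dehydrogenases Adh6a and Adh1 fell by 3.49 (SE 0.43, adjusted p = 0.00128) and 3.68 (SE 0.95, adjusted p = 0.0294), and the aldehyde dehydrogenase Aldh3a1 by 3.35 (SE 0.65, adjusted p = 0.00823). The secretoglobin Scgb1a1 fell by 3.88 (SE 0.94, adjusted p = 0.0227), the solute carrier Slc46a2 by 3.35 (SE 0.78, adjusted p = 0.0196), adenosine deaminase Ada by 3.22 (SE 0.79, adjusted p = 0.0248) and the protease inhibitor Serpinb7 by 3.17 (SE 0.59, adjusted p = 0.00724). Adh1 was 5.22 in mass 412, 10.54 in 426 and 8.53 in 510. Without mass 426 the changes were -5.30 for Ces1f, -3.57 for Adh6a, -4.90 for Adh1 and -4.33 for Aldh3a1. They were -4.27 for Scgb1a1, -3.80 for Slc46a2, -3.80 for Ada and -3.61 for Serpinb7. Of the 16 genes with the largest changes, Krt16, Defb4, Tmprss11b, Krt6a, Ces1f, Adh6a, Aldh3a1 and Serpinb7 were called without any single array, but Aldh3a1 (adjusted p = 0.0603) and Serpinb7 (0.0570) were lost with only the forestomach arrays in the fit. Scgb1a1 was lost without forestomach controls 214, 216 and 217 and mass 412 (adjusted p = 0.0706, 0.0785, 0.0646 and 0.0683), and without the same 3 controls so were Adh1 (0.0751, 0.0933 and 0.0900), Slc46a2 (0.0575, 0.0683 and 0.0637) and Ada (0.0679, 0.0806 and 0.0791). Chil4 was lost without forestomach controls 214 and 216 and masses 412 and 510 (0.109, 0.104, 0.0744 and 0.0529), and S100a8 without forestomach controls 214, 216 and 217 and masses 412 and 510 (0.0699, 0.0650, 0.0557, 0.0621 and 0.0506). Chil3 was lost without esophagus controls 216, 217 and 214, flox/flox 313, forestomach controls 214, 216 and 217 and masses 412 and 510 (0.0620, 0.0629, 0.0555, 0.0529, 0.118, 0.131, 0.103, 0.135 and 0.0913). Tspan8 was lost without esophagus controls 216 and 217, flox/flox 193 and 307, forestomach controls 214, 216 and 217 and masses 412 and 426 (0.0546, 0.0537, 0.0517, 0.0516, 0.105, 0.106, 0.105, 0.119 and 0.104).

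Among epithelial gene groups in the masses, stress keratins and alarmins rose most (14 of 19 genes above 0, median 2.76, camera adjusted p = 4.25e-06, and adjusted p = 0.368 with an estimated correlation). Of these, 10 genes were called higher and 0 lower, over all genes and adjusted over the list alone, with Defb4, Krt16, Krt17 (3.77, SE 0.52, adjusted p = 0.00214) and Krt6a at the top. Squamous differentiation fell as a group (25 of 27 below 0, median -0.56, adjusted p = 2.23e-05, and adjusted p = 0.368 with an estimated correlation), with 7 called lower and 12 adjusted over the list alone. Examples were the transcription factor Grhl1, which fell by 0.49 (SE 0.09, adjusted p = 0.00661), and the cornified envelope genes Scel and Sbsn, which fell by 0.90 (SE 0.17, adjusted p = 0.00762) and 0.9991 (SE 0.19, adjusted p = 0.00820). Xenobiotic and retinoid metabolism fell as a group (16 of 21 below 0, median -1.31, adjusted p = 0.000116, and adjusted p = 0.368 with an estimated correlation). It had 9 genes called lower, and 15 lower and 2 higher adjusted over the list alone. Gstm1, a glutathione transferase, fell by 1.82 (SE 0.27, adjusted p = 0.00238), the retinol-oxidising Adh7 by 1.31 (SE 0.20, adjusted p = 0.00293) and the cytochrome Cyp2f2 by 2.24 (SE 0.43, adjusted p = 0.00829). Lipid metabolism fell as a group (15 of 20 below 0, median -0.51, adjusted p = 0.000652, and adjusted p = 0.368 with an estimated correlation), with 9 called lower, and 11 lower and 1 higher adjusted over the list alone. The fatty acid elongase Elovl6 fell by 1.74 (SE 0.35, adjusted p = 0.00956). These 4 lists passed without any single array. Proliferation lay above 0 in 26 of 26 genes (median 0.47, adjusted p = 0.000266, and adjusted p = 0.501 with an estimated correlation), with 0 called over all genes or adjusted over the list alone (3 at an unadjusted p under 0.05), and was lost without mass 412 (adjusted p = 0.116), whose mean of 8.44 was above the 7.21 and 7.69 of the other masses.

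Junction genes of the masses moved in different directions. The desmosomal cadherins Dsc2 and Dsg3 rose by 3.40 (SE 0.25, limma adjusted p = 6.78e-05) and 1.37 (SE 0.21, adjusted p = 0.00258). Their list, with 2 genes called higher and 2 lower, and 4 and 2 adjusted over the list alone, did not pass camera (12 genes, median 0.17, adjusted p = 0.0969) but passed without mass 426 (0.0225). In the tight junction list Cldn23 fell by 1.74 (SE 0.28, adjusted p = 0.00371); 2 of 15 genes were called lower, over all genes and adjusted over the list alone, and the list did not pass (median -0.08, adjusted p = 0.647). Beta-catenin (Ctnnb1) rose by 0.44 (SE 0.10, adjusted p = 0.0196) and was lost without forestomach control 214 or 216 (0.0684 and 0.0768), with only the forestomach arrays in the fit (0.134) and with array weights (0.0552). Without mass 426 with forestomach arrays alone its adjusted p was 0.110. It was the only gene of the adherens junction list called higher, against 2 lower, and 3 and 5 adjusted over the list alone (18 genes, median -0.01 with a test direction of higher, adjusted p = 0.796). Cdh1 differed by 0.32 (SE 0.12, adjusted p = 0.106), Cdh3 by 0.80 (SE 0.38, adjusted p = 0.221), Ctnna1 by 0.26 (adjusted p = 0.232), Jup by -0.03 (adjusted p = 0.879), Krt5 by 0.31 (adjusted p = 0.152), Krt13 by -0.21 (adjusted p = 0.194) and Ptprc by 1.25 (SE 0.66, adjusted p = 0.275). Without mass 510 Cdh1 (0.0159) and Ctnna1 (0.00836) passed, and without mass 426 Cdh3 (0.0146). The basal squamous list had 0 of 15 called, also adjusted over the list alone, and 7 at an unadjusted p under 0.05 (median 0.04, adjusted p = 0.383).

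Endothelial genes of the masses lay above 0 in 14 of 14 (median 1.26, camera adjusted p = 5.20e-05, and adjusted p = 0.379 with an estimated correlation), with 1 called, Plvap (1.4967, SE 0.39, adjusted p = 0.0305). Plvap was lost without forestomach control 216 or 217 or mass 412 or 426 (0.0950, 0.118, 0.0911 and 0.0610). Fibroblast and matrix genes lay above 0 in 20 of 20 (median 1.04, adjusted p = 0.000652, and adjusted p = 0.501 with an estimated correlation), with means of 8.03, 8.13 and 6.78 in masses 412, 426 and 510 and 6.84, 6.12 and 6.10 in controls 214, 216 and 217. Activated fibroblast and pericyte genes rose as a group (12 of 13 above 0, median 1.78, adjusted p = 0.000749), with 2 called, led by Thbs1 (1.78, SE 0.38, adjusted p = 0.0136; 0.0581 without forestomach control 214). Their means were 7.78, 8.70 and 6.58 in masses 412, 426 and 510, against 6.87, 5.98 and 5.94 in controls 214, 216 and 217. Mesenchymal transition rose as a group (15 of 15 above 0, median 0.98, adjusted p = 0.000690), with 1 called, the secreted matrix protein Tgfbi (1.66, SE 0.29, adjusted p = 0.00553). The list's means were 8.12, 8.03 and 7.18 in masses 412, 426 and 510 and 7.03, 6.57 and 6.64 in controls 214, 216 and 217. Its highest mean, 8.68, was in control esophagus 214, which also had the highest fibroblast and matrix mean (9.28). This list does not tell stroma in the samples from a transition of the epithelium. Matrix proteases rose as a group (16 of 16 above 0, median 0.73, adjusted p = 5.20e-05), with 3 called and 4 adjusted over the list alone, led by the urokinase receptor Plaur (1.25, SE 0.19, adjusted p = 0.00255). The last 3 lists each had adjusted p = 0.368 with an estimated correlation. Adjusted over the list alone, 1 endothelial, 2 activated fibroblast and 1 mesenchymal transition gene passed, all higher, and 0 fibroblast and matrix genes (3 at an unadjusted p under 0.05).

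Smooth muscle and glandular stomach genes stood out in mass 426. The smooth muscle list lay above 0 in 10 of 10 (median 1.19, camera adjusted p = 0.0103, and adjusted p = 0.501 with an estimated correlation), with a mean of 8.94 in mass 426, 7.05 in 412, 6.26 in 510 and 6.80 in control 214, and was lost without 426 (0.372). Glandular stomach genes lay above 0 in 16 of 17 (median 1.74, adjusted p = 0.000400, and adjusted p = 0.501 with an estimated correlation). Their mean was 10.26 in mass 426 and between 5.52 and 6.09 on the other 12 arrays, and without 426 the median was 0.11 (adjusted p = 0.192). Mast cell genes rose as a group (7 of 7 above 0, median 0.79, adjusted p = 0.00492, and adjusted p = 0.368 with an estimated correlation) and were lost without 426 (0.117). Macrophage and monocyte genes rose as a group (14 of 15 above 0, median 0.77, adjusted p = 0.00289, and adjusted p = 0.501 with an estimated correlation) and passed without any single array. None of these 4 lists had a member called, over all genes or adjusted over the list alone; at an unadjusted p under 0.05 there were 1, 4, 3 and 1. Skeletal muscle (19 genes, median 0.09, adjusted p = 0.647), T and NK cells (11 genes, 0.13, adjusted p = 0.358) and adipocytes (7 genes, median 0.03, mean -0.34 and test direction lower, adjusted p = 0.478) did not pass and had 0 genes called by either adjustment, and 0, 0 and 2 at an unadjusted p under 0.05. MHC class II presentation (9 genes, median 0.58, adjusted p = 0.117) had 1 gene called lower by either adjustment. Langerhans and dendritic cells (9 genes, 0.25, adjusted p = 0.0692) had 1 called higher by either adjustment, and passed without flox/flox esophagus 193 or 307 (0.0435 and 0.0418), forestomach control 216 (0.0424) or mass 412 (0.0278). B and plasma cells (9 genes, 0.08, adjusted p = 0.473) had 1 called lower, and 1 higher and 1 lower adjusted over the list alone.

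**Figure D2:**
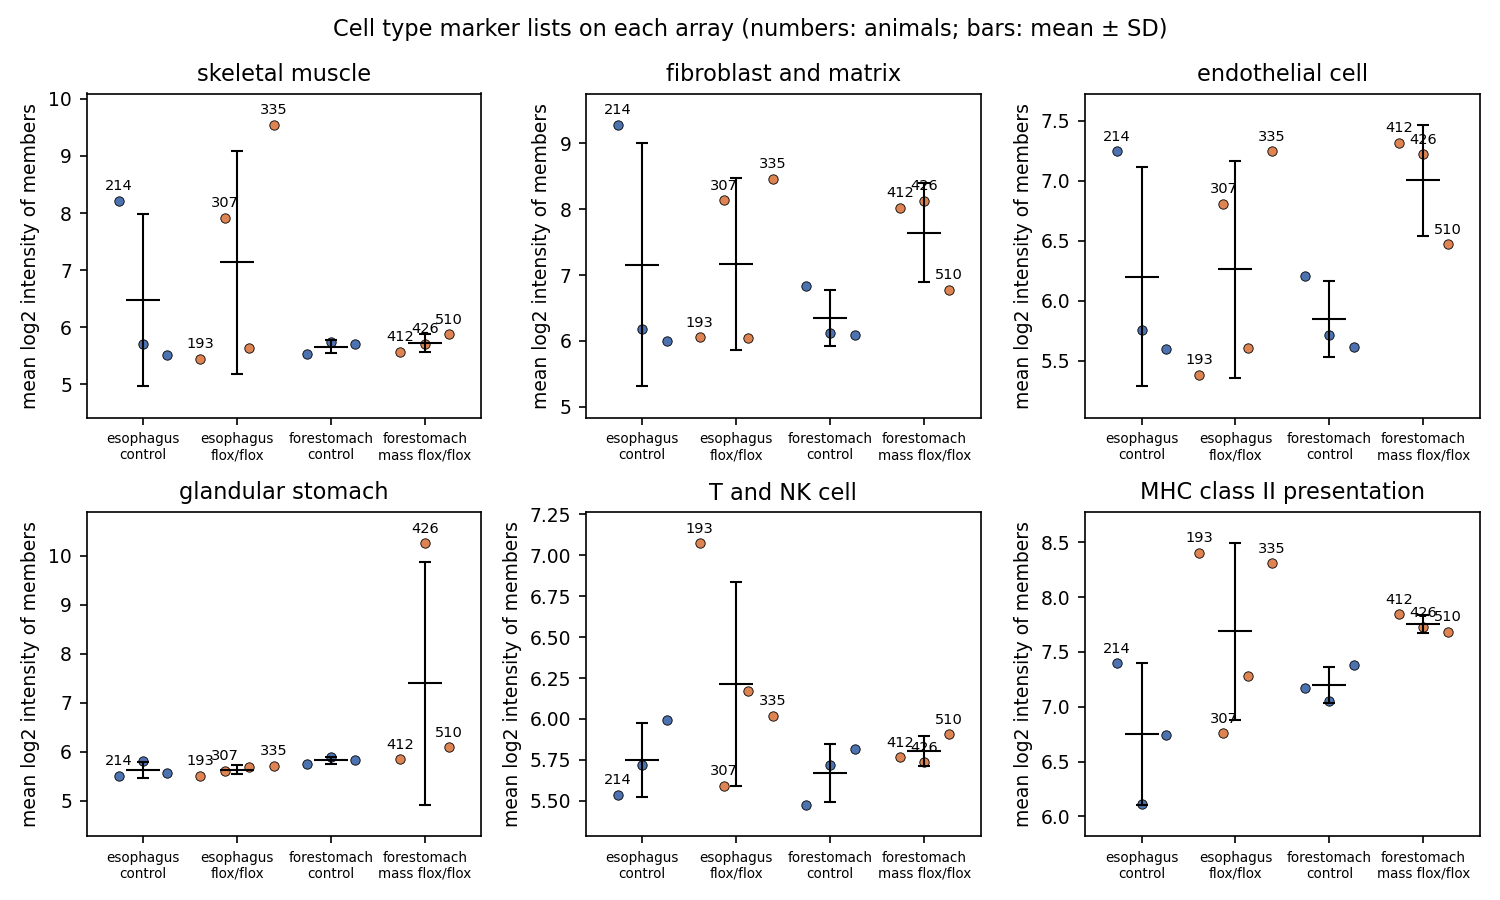
Mean log2 intensity of the tested genes of 6 marker lists on each array, by group, with animal numbers. The glandular stomach list stands at 10.26 in mass 426, and the skeletal muscle list at 8.22, 7.92 and 9.54 in esophagus arrays 214, 307 and 335.

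Response and signalling groups also moved in the masses. Hypoxia and glycolysis genes rose as a group (14 of 17 above 0, median 0.34, camera adjusted p = 0.00242, and adjusted p = 0.368 with an estimated correlation), with 5 called higher and 1 lower, and 6 and 3 adjusted over the list alone. Phosphoglycerate kinase Pgk1 rose by 0.85 (SE 0.12, adjusted p = 0.00214) and Ndrg1 by 1.57 (SE 0.26, adjusted p = 0.00426), while adrenomedullin Adm fell by 2.06 (SE 0.40, adjusted p = 0.00899). The immediate early and handling response fell as a group (16 of 19 below 0, median -0.55, adjusted p = 0.00193, and adjusted p = 0.368 with an estimated correlation), with 4 called lower and 5 adjusted over the list alone, led by Ier2, which fell by 1.11 (SE 0.23, adjusted p = 0.0127; 0.0586 and 0.0565 without forestomach controls 214 and 216). Controls 214 and 216 carried this fall, with list means of 9.08 and 8.95, against 8.39 in control 217 and 8.09 to 8.27 in the masses. NF-kappaB target genes rose as a group (13 of 17 above 0, median 0.40, adjusted p = 0.00264, and adjusted p = 0.368 with an estimated correlation), with 4 called higher and 1 lower, and 7 and 1 adjusted over the list alone. They were led by Bcl3, a nuclear regulator of NF-kappaB (1.33, SE 0.14, adjusted p = 0.000552), and the list was lost without mass 412 (0.0532). Cytokines and chemokines rose as a group (17 of 21 above 0, median 0.30, adjusted p = 0.0103, and adjusted p = 0.368 with an estimated correlation; 0.0857 without mass 510). Interferon-stimulated genes rose as a group (12 of 15 above 0, median 0.26, adjusted p = 0.0291, and adjusted p = 0.501 with an estimated correlation; 0.220 without mass 426 and 0.0745 with sex as a covariate). Both lists had 0 members called by either adjustment, and 7 and 3 at an unadjusted p under 0.05. The Notch pathway fell as a group (9 of 12 below 0, median -0.19, adjusted p = 0.0324, and adjusted p = 0.368 with an estimated correlation), with 4 called lower and 5 adjusted over the list alone, led by Hes1, which fell by 0.69 (SE 0.13, adjusted p = 0.00670). The Notch list was lost without forestomach control 214 or mass 426 or 510 (0.0817, 0.117 and 0.0792).

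Of the lists that did not pass in the masses, EGFR ligands and receptors (13 genes, median -0.12, camera adjusted p = 0.515) held 1 gene called higher and 2 lower, and 2 and 2 adjusted over the list alone. The ligands epiregulin (Ereg) and betacellulin (Btc) fell by 1.80 (SE 0.31, adjusted p = 0.00523) and 0.81 (SE 0.15, adjusted p = 0.00714). The neutrophil and immature myeloid list (11 genes, median 0.19, adjusted p = 0.115; 0.0470 without forestomach control 216) had 1 gene called each way by either adjustment; the decoy receptor Il1r2 fell by 1.69 (SE 0.36, adjusted p = 0.0124). Wnt and beta-catenin targets had a median of 0.02 with a mean of -0.08 and a test direction of lower (16 genes, adjusted p = 0.647), with 3 called lower by either adjustment, led by Lgr6, which fell by 0.78 (adjusted p = 0.0136; 0.0618 without forestomach control 217). With fry, 9 lists of the forestomach comparison passed, the desmosome (adjusted p = 0.0182) and 8 that passed camera at the preset correlation. These 8 were stress keratins, squamous differentiation, xenobiotic and lipid metabolism, matrix proteases, hypoxia and glycolysis, the immediate early response and Notch. Other splits of the forestomach arrays passed a median of 7 lists, and at most 17, by camera at the preset correlation.

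The forestomach count was 753, 829 and 810 without forestomach controls 214, 216 and 217, and 2232 without mass 510. The higher genes among them, 366 in all, were 708 without mass 510, 563 (of 1843) without 426, 218 (of 1190) without 412, and 149, 129 and 148 without forestomach controls 214, 216 and 217. With sex as a covariate, where 1 of 3 controls and 2 of 3 masses were female, the count was 1363. Of the 67 called genes named by the rule, 9 were then lost, among them Adh1 (adjusted p = 0.0545), Chil3 (0.0776) and Chil4 (0.0519). With only the forestomach arrays in the fit it was 452, and 29 of the 67 called genes named by the rule were still called.

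**Figure D3:**
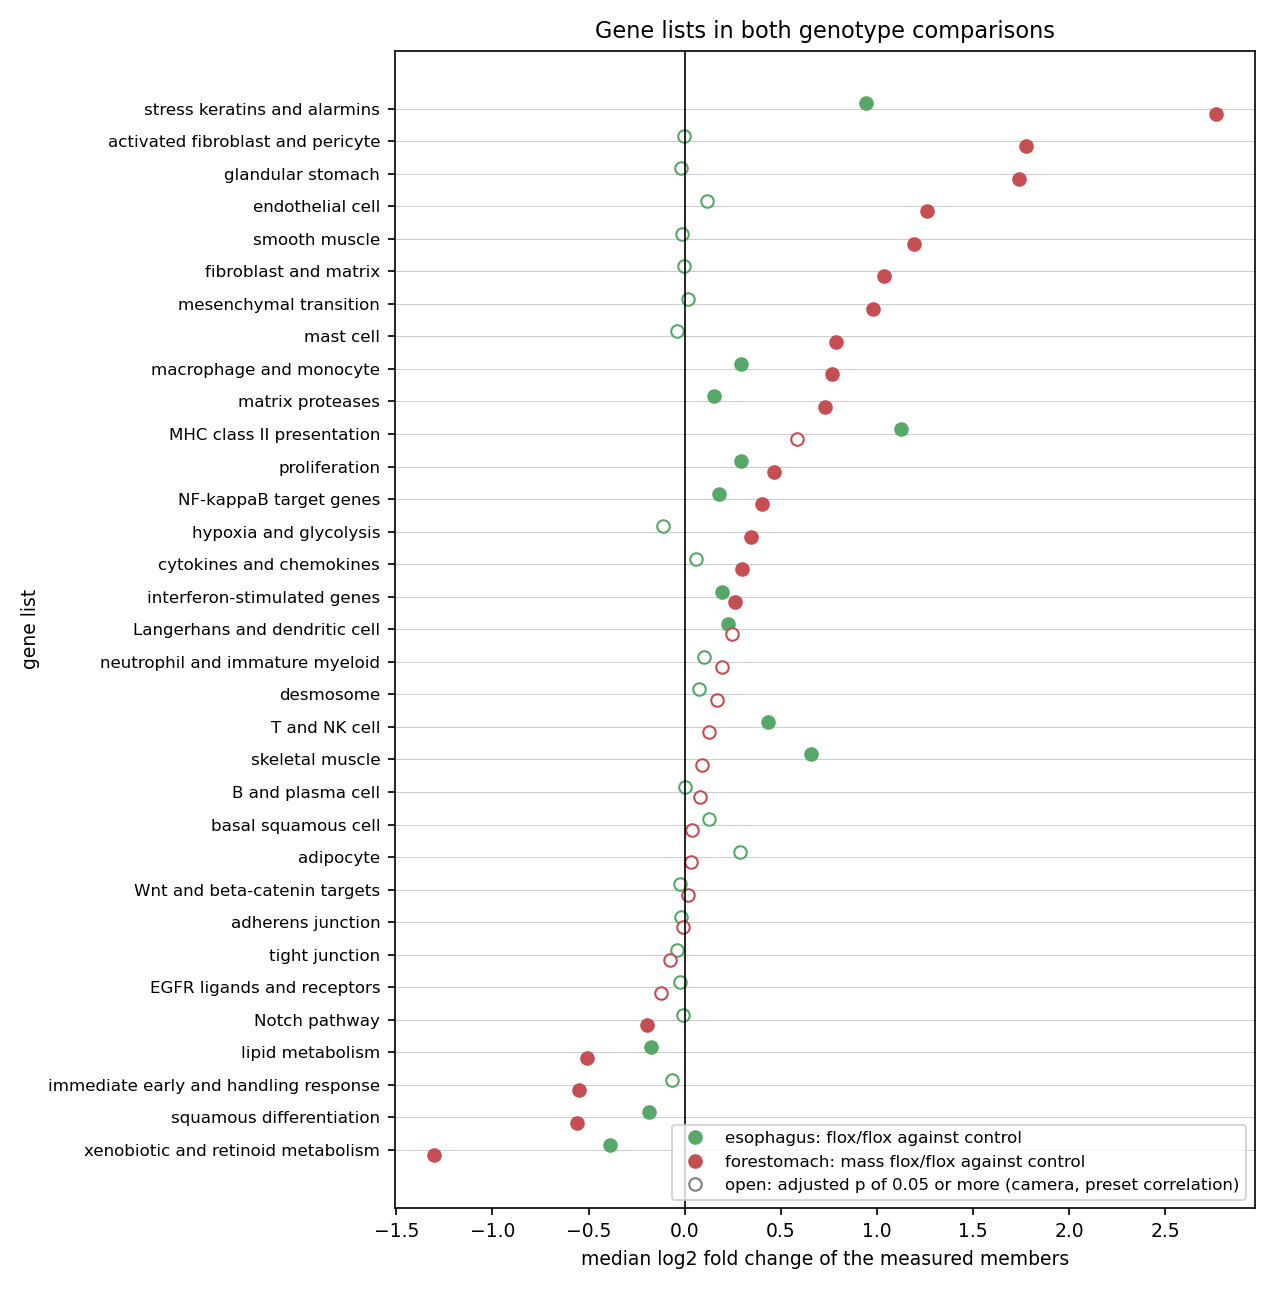
Median log2 change of 33 of the 34 tested gene lists in the esophagus and in the forestomach comparison; filled symbols passed camera at the preset correlation and open symbols did not. Stress keratins and alarmins stand at 0.94 in the esophagus and 2.76 in the masses, and xenobiotic and retinoid metabolism at -0.39 and -1.31.

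The change in the masses and the change in the esophagus were compared by testing their difference, which passed for 22 genes, 13 higher and 9 lower. Defb4 differed most (6.01, SE 0.51, limma adjusted p = 0.00117), at 12.82 and 12.66 in control and flox/flox esophagus and 4.99 and 10.84 in control forestomach and masses. Dsc2 (2.95, SE 0.34, adjusted p = 0.00392), the GPI-anchor remodelling gene Cwh43 (3.15, SE 0.46, adjusted p = 0.0208), tissue factor F3 (3.05, SE 0.48, adjusted p = 0.0352) and the sphingolipid enzyme Sptlc3 (2.71, SE 0.29, adjusted p = 0.00284) also differed upward. Downward differences were largest for Dab1 (-2.49, SE 0.33, adjusted p = 0.0113), the alcohol dehydrogenase Adh6b (-2.33, SE 0.25, adjusted p = 0.00284), Orm1 (-1.97, SE 0.23, adjusted p = 0.00412), the retinol dehydrogenase Rdh1 (-1.86, SE 0.19, adjusted p = 0.00284) and Arxes2 (-1.63, SE 0.27, adjusted p = 0.0456). These 5 genes averaged between 4.80 (Orm1) and 5.55 (Rdh1) in control esophagus, near the level filter of 5, so that a fall there could not have been measured, and between 6.80 (Arxes2) and 8.34 (Dab1) in control forestomach. Defb4 and Dsc2 already averaged 12.82 and 11.99 in control esophagus. A rise there as large as in the masses would exceed the highest intensity on any array, so it could not have been measured either. The count was 372 without mass 510 and 139 without 426, 14, 11 and 15 without esophagus controls 214, 216 and 217, 11 without flox/flox 335, 33 without mass 412, 15, 10 and 15 without forestomach controls 214, 216 and 217, and 145 with the animal as a random block. Arxes2 was lost without esophagus controls 216 and 214 (0.139 and 0.100), flox/flox 193, 307 and 335 (0.0907, 0.0911 and 0.0724), forestomach controls 214, 216 and 217 (0.127, 0.0793 and 0.107) and mass 412 (0.0563). Cwh43 was lost without esophagus controls 216, 217 and 214 (0.0937, 0.0589 and 0.0545), flox/flox 335 (0.0555) and forestomach controls 214 and 216 (0.0663 and 0.0586). F3 was lost without esophagus controls 216, 217 and 214 (0.108, 0.0818 and 0.0899), flox/flox 193, 307, 313 and 335 (0.0827, 0.0533, 0.0735 and 0.0735) and forestomach controls 214, 216 and 217 (0.109, 0.122 and 0.0735).

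For gene lists, the difference passed camera for 16 of 34 and for 0 with an estimated correlation. Hypoxia and glycolysis (0.58, adjusted p = 4.84e-05, and adjusted p = 0.168 with an estimated correlation), stress keratins (1.59, adjusted p = 4.20e-05), endothelial cells (1.19, adjusted p = 4.20e-05), mesenchymal transition (0.86, adjusted p = 0.000423) and activated fibroblasts (1.41, adjusted p = 0.000467) passed without any single array. The last 4 each had adjusted p = 0.481 with an estimated correlation. Hypoxia and glycolysis also passed fry (adjusted p = 0.0465). Adjusted over the list alone it had 7 genes higher and 1 lower.

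Between the 2 tissues of the same control animals, 1059 genes differed, 558 higher in forestomach and 501 higher in esophagus. Krt1, a keratin of cornifying epithelium, was higher in forestomach, at 13.89 against 6.47 (log2 7.42, SE 0.35, limma adjusted p = 4.35e-07), as were Krt10 (6.22, SE 0.51), carbonic anhydrase Car2 (7.37, SE 0.37), the lipase Lipn (6.85, SE 0.45) and Abhd12b (5.58, SE 0.70). Defb4 was higher in esophagus, at 12.82 against 4.99 (-7.83, SE 0.37, adjusted p = 4.35e-07), as were the claudin Cldn17 (-5.21, SE 0.62), F3 (-5.08, SE 0.35), Tmprss11b (-4.86, SE 0.68) and Sptlc3 (-4.80, SE 0.21). In Car2, Lipn, Abhd12b, Defb4 and Tmprss11b the lower tissue lay under the level filter. All 10 genes were called without any single array. The count was 543, 600 and 589 without forestomach controls 216, 214 and 217, 638, 654 and 580 without esophagus controls 216, 214 and 217, and 1551 and 1565 without masses 412 and 510. With the animal as a fixed block it was 2348 and as a random block 2670.

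The changes in the 2 flox/flox tissues were related across genes. Lrrfip2 was the 1 gene called in both, lower in each (-0.84 in esophagus and -0.72, SE 0.11, adjusted p = 0.00338 in the masses) (chance would give 0.168 if the comparisons were independent, but they share control animals). The overlap was 5 genes without flox/flox 307 and 0 without esophagus control 216 or 217, flox/flox 193, 313 or 335, any forestomach control or any mass. The changes correlated at r = 0.534, and their ranks at 0.449, over 15875 genes, which are not independent replicates. Of the 366 genes higher in the masses, 297 (81.1%) lay above 0 in the esophagus, with a median of 0.20. Of the 1334 lower genes, 1130 (84.7%) lay below 0, with a median of -0.17. Simulated data with shared control animals and no change gave an equal sign in 72.8% on average, and at most 75.4% in 100 draws, of the 1700 genes with the largest forestomach statistic. The covariance was 0.0733, against 0.00759 expected from the deviations of the shared animals and 0.0166 in the simulated data, which gave r = 0.291 on average and at most 0.344. On the real arrays many genes move together, and a split of esophagus arrays 214, 307 and 335 against the rest called 507 genes. The highest values of the draws are therefore not taken as bounds. With no control animal in both comparisons, the 6 ways to divide the 3 animals gave r between 0.0220 and 0.550. The lowest had control 214 alone for the esophagus, whose array was rich in muscle genes, and the next was 0.334. This division was chosen after the data were seen.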

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

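Among the results below, the tests on mass 426, on esophagus tissue in the masses and on genes that moved together, and the sorting of splits by forestomach group, were chosen after the result was seen; the splits of the arrays and the test on shared control arrays were planned.

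Some arrays stood apart from their group in flox/flox esophagus. For 3 of 45 values tested, the gap of the farthest array to its nearest neighbour passed the limit of the Dixon test, where chance gives about 1 in 20, or 2.25. In Sdc3 the gap was 0.862 of the range, with animal 193 highest. In the mean of the mast cell list it was 0.835, with animal 335 highest, and in the mean of the Notch list 0.880, with animal 335 lowest.

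The change of the masses against control forestomach differed from that of flox/flox against control esophagus in 22 genes, and the difference was tested directly. All flox/flox forestomach samples were masses, so an effect of genotype cannot be told apart here from one of the mass. The 10 named genes differed by 6.01 (Defb4), 3.15 (Cwh43), 3.05 (F3), 2.95 (Dsc2), 2.71 (Sptlc3), -2.49 (Dab1), -2.33 (Adh6b), -1.97 (Orm1), -1.86 (Rdh1) and -1.63 (Arxes2). In control esophagus the 5 genes with a negative difference averaged 5.31 (Dab1), 5.30 (Adh6b), 4.80 (Orm1), 5.55 (Rdh1) and 5.37 (Arxes2), near the filter of 5, where a fall could not have been measured, so for these 5 the difference does not show another effect of genotype there. Nor does it for Defb4 and Dsc2, at 12.82 and 11.99 in control esophagus. A rise there as large as in the masses would exceed the highest intensity on any array. Of 100 drawn splits, the real one included, 12 called at least 22 genes (highest 1538) and 19 passed at least 16 lists (highest 20). These splits do not decide whether chance gives such counts, because 10 of the 11 other splits with as many genes, and 8 of the 18 with as many lists, kept the forestomach groups or turned them round and so carried the change in the masses. Of the 89 splits that mixed the forestomach groups, 1 called as many genes (79), with esophagus arrays 214, 307 and 335 on 1 side, which points to a structure of the samples, and 10 passed as many lists (highest 18).

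Of the 16 lists with different effects in masses and esophagus, 15 are given here as the median difference. They were stress keratins and alarmins (1.59), activated fibroblasts and pericytes (1.41), endothelial cells (1.19), mesenchymal transition (0.86) and hypoxia and glycolysis (0.58), which passed camera without any single array. Glandular stomach (1.66) was lost without mass 426 (adjusted p = 0.161), as were smooth muscle (1.17; 0.399) and mast cells (0.72; 0.0702). Smooth muscle was also lost without esophagus control 214 (0.250) or flox/flox 313 (0.0503), and fibroblasts and matrix (1.07) without esophagus control 214 (0.273). Matrix proteases (0.56) were lost without mass 412 (0.128), and without mass 510 so were cytokines and chemokines (0.13; 0.150) and the immediate early response (-0.40; 0.0574). Squamous differentiation (-0.16) was lost without esophagus control 216, flox/flox 307 or 313, forestomach control 214 or mass 412 or 426 (0.0842, 0.139, 0.0880, 0.0643, 0.258 and 0.0702). Lipid metabolism (-0.33) was lost without the same arrays (0.0697, 0.0823, 0.0678, 0.0531, 0.0549 and 0.117), and xenobiotic and retinoid metabolism (-0.78) without esophagus control 216, flox/flox 307 or 313, forestomach control 214 or mass 412 or 510 (0.0919, 0.148, 0.0838, 0.0594, 0.199 and 0.372). With an estimated correlation the adjusted p of these 16 lists lay between 0.168 and 0.587.

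Of 8645 tested probe sets not listed with a single gene, 51 were called in the forestomach comparison, 11 higher and 40 lower; in the esophagus limma called 0, with 378 at an unadjusted p under 0.05.

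In the shift of the masses towards control esophagus, of 58 genes at least 4-fold higher in control esophagus than in control forestomach, 47 (81.0%) lay above 0 in the masses (median 0.98), and of 77 genes 4-fold higher in control forestomach 70 (90.9%) lay below 0 (median -1.51). Genes near the floor in control forestomach could hardly fall, and of genes above 7 in both control tissues, 9 of 15 (60%) and 19 of 19 moved that way, so that a loss of forestomach-high genes together with a gain of esophagus-high genes stays open for the gain. Each control animal in turn was also kept out of the choice by fold and used alone as the control of the masses. The shares were then 56.25% to 70% for the gain and 92.9% to 95.7% for the loss. The control arrays shared by the contrasts gave 10.1% of the covariance of 0.112, which argues against them as the cause. Esophagus tissue in the samples was tested on 19 genes 8-fold higher in esophagus, whose values imply shares of esophagus RNA from -0.70% (Ces1b) to 319% (Anxa8) with a median of 25.5%; a test set first, that of genes under 1/3 of the median, gave 26.3% and decided nothing, and a wider one chosen after that, of genes under 1/3 or over 3 times the median, gave 52.6%. This argues against mixing as the whole cause and not against some mixing, and a change of the epithelium itself may account for part of it, which these tests leave open.

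Glandular stomach genes were high in mass 426. Genes of parietal, chief and endocrine cells exceeded the highest other array by more than 1 log2 in 5 of 6 cases, with Pgc at 11.60 (excess 6.68), Atp4a at 11.51 (5.19), Atp4b (3.53), Cblif (3.45) and Ghrl (2.19), and Chga did not (0.47). Mucous genes were also high, with Tff1 at 13.39 and Gkn1 at 13.08. All 4 of the parietal and chief cell genes exceeded it, which argues against a gain of mucous genes alone. Glandular mucosa taken with the sample is a candidate source, and whether it belonged to the mass or lay beside it was not tested.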

How the results depend on the processing

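The alternatives with sex, with the muscle mean, without the 3 muscle-rich esophagus arrays, without mass 426 and with the controls divided were chosen after seeing the data. Camera on the ranked statistics was not planned either. Low intensity limits genes near background: 4059 genes were not tested, and folds from a control mean under the filter are uncertain. For named genes, 1348 of the values under other settings and 1156 with 1 array left out kept direction and side of the threshold, 207 and 206 lost the call, 1 and 3 gained it, and 0 reversed. For lists, 1103 and 1219 were kept, 110 and 60 lost, 23 and 45 gained, and 1 and 2 reversed. Except where fewer genes, fewer arrays or a stricter threshold is the alternative itself, the cause was not tested.

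The esophagus count of 2 was 0 with only the arrays compared (1465 at an unadjusted p under 0.05 by limma), 0 at an adjusted p under 0.01, 0 with sex (865 at unadjusted p) and 0 with the muscle mean (1128) as a covariate. It was 1 with a 2-fold minimum and 1, a different gene, without the 3 muscle-rich arrays. With sex as a covariate Sdc3 changed by -1.07 (SE 0.14) and Lrrfip2 by -0.83 (SE 0.12); with the muscle mean they changed by -1.06 (SE 0.14) and -0.79 (SE 0.10). The forestomach count of 1700 was 452 with only the arrays compared, 1102 with array weights, 475 with a 2-fold minimum, 552 at an adjusted p under 0.01 and 741 without mass 426 with forestomach arrays alone (1843 without mass 426 in the fit of all arrays). With quantile normalization it was 1619, of which 31.8% were higher, against 21.5%. The difference count of 22 was 101 with the stricter filter, 49 with quantile normalization, 56 with trend and robust, 60 with array weights, 46 with sex and 9 at an adjusted p under 0.01. Of the 22 genes 59.1% were higher, against 48.98% with quantile normalization, 44.4% of the 27 with median centring, 41.3% with sex, 40% with array weights, 30.7% with the stricter filter and 30.4% with trend and robust. The control tissue count of 1059 was 2273 with only the arrays compared, 3802 with array weights, 402 with a 2-fold minimum and 459 at an adjusted p under 0.01.

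Pairing by animal, as a random block with a correlation of 0.396, gave 0 genes in the esophagus (1074 at an unadjusted p under 0.05 by limma), 1622 in the forestomach, 145 for the difference (30.3% higher) and 2670 for the control tissues; a fixed block gave 2348. The block ended the calls of Sdc3, Lrrfip2, Jun and Zfp36 and of no other named gene. Camera on the ranked statistics passed 13, 21 and 17 lists with the block and 13, 21 and 18 without.

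Of the lists, 13, 20 and 16 passed in the esophagus, the forestomach and the difference. With an estimated correlation 0, 0 and 0 passed, and with fry 0, 9 and 1; with the stricter filter 10 passed for the difference. In the esophagus, sex as a covariate ended 5 of the 13 and the muscle mean 2, apart from the muscle list itself, which it removes by design. The median of the skeletal muscle list in the esophagus, 0.66, was -0.0496 without the 3 muscle-rich arrays (adjusted p = 0.457) and -0.126 without flox/flox 335; with 1 array left out it ran up to 1.48. The fibroblast and matrix median, -0.00, was 0.891 without control 214, and the lowest was -0.53, without control 217.

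With 1 array left out, the counts ran from 0 to 7 in the esophagus, 753 to 2232 in the forestomach, 10 to 372 for the difference, 543 to 1565 for the control tissues and 0 to 5 for the overlap. The lists that passed ran from 7 to 16, 16 to 22 and 13 to 19.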

Other observations

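Apart from the splits of the arrays and the test on the neighbours of Ctnnd1, which were planned, the tests and gene families in this part were chosen after the results were seen. Gene families were formed from symbols that share a stem and have at least 8 tested members. In the masses, 14 of 19 genes of the late cornified envelope family (Lce) were called lower and 0 higher (hypergeometric test, adjusted p = 1.61e-09), with a median change of -1.61. Peroxisome biogenesis genes (Pex) followed, with 8 of 14 called lower (median -0.43, adjusted p = 0.000581), and hydrolases of the nudix family (Nudt), with 9 of 21 (median -0.40, adjusted p = 0.00198). All 3 medians stayed below 0 with quantile normalization (-1.63, -0.39 and -0.40), where 12, 8 and 8 genes were called lower, and with median centring (-1.62, -0.44 and -0.41), where 13, 7 and 10 were. Without forestomach controls 214, 216 and 217 the Lce genes called lower were 4, 5 and 7, and without masses 412, 426 and 510 they were 6, 9 and 17. The Nudt genes called lower were 6, 5 and 4 without those controls and 5 without mass 412. Whether probe sets of near-identical Lce members read each other's transcripts was not tested, and the hypergeometric test counts each gene of a family as independent, so its p-values are lower than they would be if members shared signal. In the esophagus the medians were -0.05, -0.10 and -0.08, and limma called 0 members.

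Several genes that rose in the masses were also high on flox/flox esophagus arrays. Array 307 was an exception for Chil4 and S100a8, but for Krt6a it also lay above the controls. Chil4 was 13.61, 10.15 and 13.63 in animals 193, 313 and 335, 5.28 in 307 and between 5.32 and 6.78 in controls. S100a8 was 11.24, 7.17 and 9.24 in the same animals, 5.82 in 307 and between 5.41 and 5.85 in controls. Krt6a was 10.87, 10.33 and 10.91 in them, 8.33 in 307 and between 6.01 and 6.496 in controls. None of the 3 genes was called in the esophagus.

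Few genes were called in the esophagus, 2 against 1700 in the forestomach. Muscle RNA in 3 arrays was tested with the mean of the skeletal muscle list as a covariate. This left 0 genes called by limma (1128 against 1108 at an unadjusted p under 0.05) and argues against muscle RNA as the whole cause. No covariate for stroma was fitted, so stroma RNA stays open. The spread of the masses in the pooled fit stays open, since array weights gave 3 genes, but 1935 at an unadjusted p under 0.05 and a smallest adjusted p of 0.00379 against 0.0400, while a fit of the esophagus arrays alone, with fewer degrees of freedom, called 0 by limma (1465 at an unadjusted p under 0.05, smallest adjusted p = 0.134). Whether the array of flox/flox animal 307 is a control cannot be told apart, as the values go both ways. Its Ctnnd1 value, 9.95, was the lowest of the 7 esophagus arrays and lay 2.27 prediction errors below the control mean. Of the 7 genes called without this array, it lay 5.92 (Sdc3) and 4.51 (Lrrfip2) prediction errors from the controls on the flox/flox side, but under 2 from them and over 3 from the other flox/flox arrays in the remaining 5 (Dbil5, Il13ra1, Krt6b, Rnase2b and Steap4).

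Of the 35 splits of the 7 esophagus arrays, 5 called at least 2 genes, the highest 507, and 13 passed at least 13 lists, the highest 18, so chance is not excluded for either count. The splits other than the real one passed a median of 11 lists. The split with 507 genes set arrays 214, 307 and 335 against the rest, which points to a structure of the samples that follows the muscle list.

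In the forestomach the real split gave 1700 genes and 20 lists. The highest of the others gave 0 genes and 17 lists, and their median was 7 lists. In the control tissues the real split gave 1059 genes and the others 0, including 3 others that part all pairs of tissues. Each design has 10 splits, and 1 of 10 reached the real value in each case, which is too few splits for a share under 0.05. Among the 100 tested genes nearest to Ctnnd1, 2 had an unadjusted p under 0.05 by limma and the same sign in both genotype comparisons, 0.552 times the share of all genes (3.62%). This argues against a flanking segment that changes many of these genes. A segment that changes only a few of them could not be seen in such a share and is not excluded.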
